A study of Homo sapiens with 36 samples.

How the data were processed

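Gene expression was measured on 36 arrays of an Affymetrix human expression array plate, read by a service laboratory per the labels' protocols. The samples were 12 breast cancer cell lines, each kept for 16 h in 0.1% DMSO, in 1 nM oestradiol (E2) or in 10 nM E2, with 1 array per line and exposure. Per the labels, the lines were maintained in 10% foetal calf serum, or 20% for MDA-MB-134-VI, MDA-MB-361 and BT-483, the latter 2 with added insulin, and were moved to charcoal-stripped, phenol red-free serum before exposure. The values were log2 expression levels as deposited by the authors, with 54675 probe sets per array, and all 36 value columns matched a sample. The software and the method of normalization behind them were not given in the sources used here. The values carry no measure of depth, so the number of lines limits the precision.

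Probe sets were named through the platform annotation of 2016, with symbols updated through a gene table of assembly GRCh38.p14, from which no coordinates were taken. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not in the annotation table. Those with several or no symbols were left out. Each of 19775 genes was represented by its probe set of highest mean over the 36 arrays. The lowest 40% of these means, under a log2 level of 5.47, were left out of the tests, which left 11865 genes. Some genes that matter for oestrogen signalling, among them AREG and AR, were not in the table and were not analysed here.

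The cell line was the replicate. The samples were paired because every line, as the same cell line, carried each exposure once per the labels, so the fits were made on within-line differences. The main test was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on the log2 difference of each line, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on adjusted p. This was done for 10 nM against DMSO, 1 nM against DMSO and 10 nM against 1 nM over the 10 lines labelled ER-positive. ER stands for oestrogen receptor, encoded by ESR1. The 2 lines labelled ER-negative were tested with the spread shared over all 12 lines. The interaction compared the change, averaged over both doses, between the ER labels. The DMSO arrays were compared between the labels in an unpaired fit. A fit per cell line set the mean of both E2 arrays against the DMSO array, with the spread taken from the differences between the 1 and 10 nM arrays of all 12 lines on 12 residual degrees of freedom. All p-values measure the spread between lines, or between the E2 arrays of a line, and none covers repeated cultures of a line, since each had 1 array per exposure.

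Gene lists, 23 in all, were written before the data were examined, as were the designs, the alternatives other than those named below and the rule for named genes. For each list the mean change over its measured genes was taken per line and tested over lines by an exact two-sided sign-flip permutation test, with Benjamini-Hochberg adjustment over the 23 lists. With 10 lines the smallest possible p was 0.00195 and with 8 lines it was 0.00781. Differences of the lists between the ER labels in DMSO were tested by an exact two-sided permutation of the label over 66 assignments, with a smallest possible p of 0.0152. The change of the spike level was set against the oestrogen-induced shift after the data were seen. Correlations over lines were tested two-sided by permutation with 100000 resamples for 10 lines and exactly over all orders for 8 lines. A list's change within 1 line was set against 10000 random lists of the same size matched on mean level. A score of luminal minus basal character was the mean level of the luminal list minus that of the basal and mesenchymal list on each array. The spread of each array, the probe sets at the 3′ and 5′ ends of GAPDH and actin, and the 24 probe sets of the poly-A spike controls, added before labelling, served as checks of quality.

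Genes were named by a rule: for each E2 comparison in ER-positive lines the 10 largest rises and 10 largest falls among genes past the threshold, 5 and 5 for the remaining comparisons, up to 4 members of each list with a described shift, and a fixed set of ER targets whatever their values. Any other gene is said to have been chosen after its values were seen or outside this rule. Genes on the Y chromosome and XIST were not reported.

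The alternatives tried were quantile normalization, centring of each array on its median, no filter on dim genes or a filter at 60%, the mean of all probe sets of a gene or every probe set by itself, eBayes with trend and robust settings, a fit without the pairing, all 3 exposures in 1 fit, the ER-negative lines alone, each dose alone, the median in place of the mean of a list, camera with a preset correlation of 0.01 or an estimated one, leaving out MDA-MB-175-VII and leaving out each line in turn. Chosen after the data were seen were the comparison over 8 lines without MCF-7 and MDA-MB-175-VII, weighting of lines by arrayWeights, and the change of the spike level as a covariate. The scripts were tested on simulated data with 200 changed genes among 11865. For the 10 nM comparison over 8 lines, 88 of 100 genes simulated with a change of 0.5 and 100 of 100 with a change of 1 log2 unit were recovered, with 18 calls among unchanged genes. For the 1 nM comparison these numbers were 93, 100 and 12. The simulated genes were drawn at random and changed alike in all 8 lines, with normal noise of each gene's own spread. The recovery therefore does not hold for genes whose response differs widely between lines, as that of many ER targets did. The figures were drawn with matplotlib 3.10.9.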

Results

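The data covered the response of 12 breast cancer cell lines to E2, the main natural oestrogen, at 1 and 10 nM for 16 h against 0.1% DMSO. Each line gave 1 array per exposure, 36 in all. The labels call 10 lines ER-positive, namely MDA-MB-361, CAMA-1, BT-474, HCC1428, T47D, MDA-MB-415, BT-483, MDA-MB-134-VI, MCF-7 and MDA-MB-175-VII. The lines BT-20 and MDA-MB-157 are labelled ER-negative. The layout asks which genes E2 changes in lines with the receptor, whether 1 and 10 nM differ, and whether lines without it respond.

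On 35 arrays the values had a standard deviation of 2.03 to 2.11 and a median of 5.12 to 5.18 on the log2 scale. The DMSO array of MCF-7 had a standard deviation of 1.46 and a median of 5.32. On that array the 3′ probe set of the housekeeping gene GAPDH lay 3.69 above the 5′ probe set, against -0.57 to 0.29 on the other 35 arrays. For actin the distance was 5.82 against 1.30 to 2.66. The array correlated with the E2 arrays of MCF-7 at r = 0.607 to 0.610 across probe sets, which are not independent, while the 1 and 10 nM arrays of MCF-7 correlated at 0.997. Within each of the 11 other lines the correlations were 0.967 or higher. All changes of MCF-7 rest on that DMSO array. No 2 arrays held identical values (0 found). The poly-A spike level ran from 5.71 to 8.78 over the 36 arrays, and its E2 minus DMSO difference was 0.42 ± 0.90 (SD, n = 10 lines, exact two-sided sign-flip p = 0.178).

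**Figure D1:**
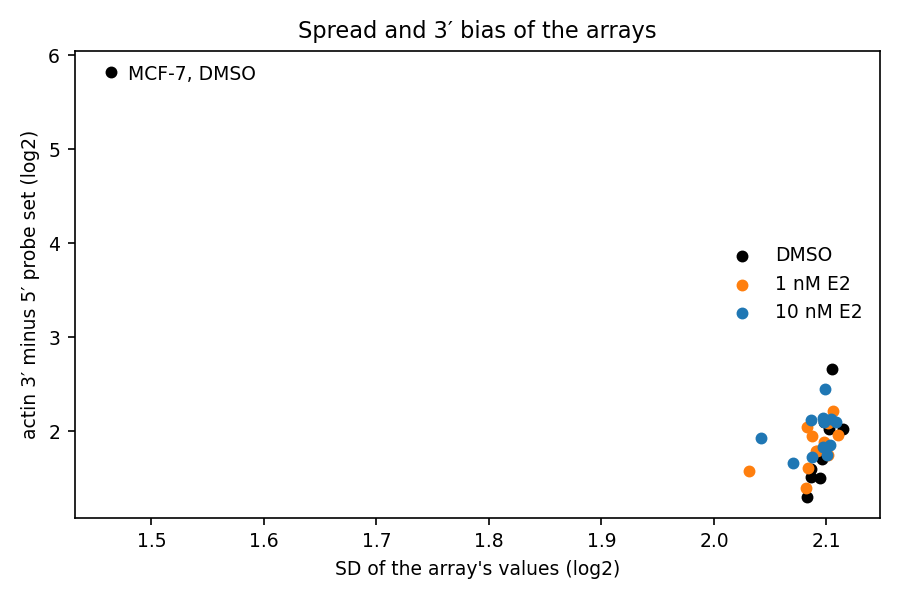
Standard deviation of each array's log2 values (x axis) against the actin 3′ minus 5′ difference in log2 units (y axis) for 36 arrays, 1 point per array, coloured by exposure. The DMSO array of MCF-7 lies at 1.46 and 5.82, and the other 35 lie at 2.03 to 2.11 and 1.30 to 2.66.

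ESR1, the gene of the oestrogen receptor, had a DMSO level of 10.14 ± 1.00 (SD) in the 8 ER-positive lines other than MCF-7 and MDA-MB-175-VII, from 8.80 in MDA-MB-415 to 11.71 in MDA-MB-134-VI. In the line labelled MDA-MB-175-VII, ESR1 stood at 3.61, with 3.97 for FOXA1 and 4.21 for GATA3, the transcription factors that mark luminal cells. That line had high levels of the mesenchymal genes VIM at 13.85 and FN1 at 12.71, and low CDH1, the epithelial cadherin, at 4.78. The line labelled MDA-MB-157 had ESR1 at 8.56, FOXA1 at 8.94, GATA3 at 11.80, CDH1 at 12.48 and VIM at 6.99. BT-20 had ESR1 at 7.62 together with the basal genes EGFR at 11.44 and KRT5 at 8.67. FOXA1, GATA3, CDH1, VIM, FN1, EGFR and KRT5 belong to the fixed luminal and basal lists but were picked outside the rule for named genes. The luminal minus basal score, as the mean of 3 arrays, was 4.13 for the line labelled MDA-MB-157, -4.45 for MDA-MB-175-VII and 0.12 for BT-20, against 1.47 to 4.95 for the 8 lines. Both names are used below for the lines so labelled, since the score of MDA-MB-157 lay within the range of the 8 lines and that of MDA-MB-175-VII below BT-20. ERBB2, the gene of the HER2 receptor, was highest in BT-474 at 12.34 and MDA-MB-361 at 11.79.

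**Figure D2:**
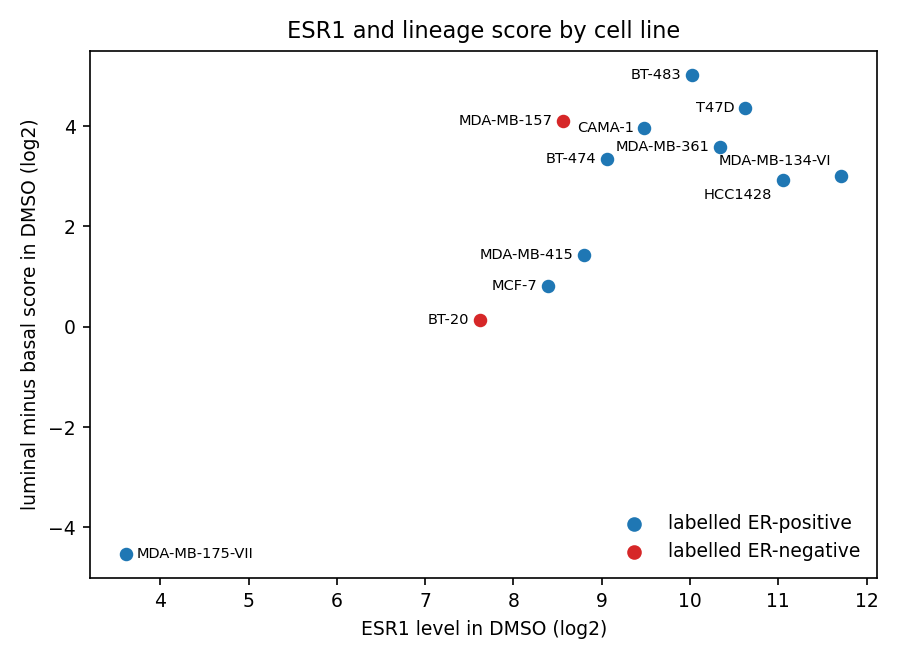
Level of ESR1 (x axis) against the luminal minus basal score (y axis), both on the log2 scale in the DMSO arrays, 1 point per cell line, coloured by ER label. The line labelled MDA-MB-175-VII lies at 3.61 and -4.53, and the line labelled MDA-MB-157 has ESR1 at 8.56.

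Between the ER labels in DMSO, GREB1, a cofactor that ER induces, had a level of 7.84 ± 1.92 (SD) in the 10 ER-positive lines and of 3.09 in BT-20 and 3.49 in MDA-MB-157. PGR, the gene of the progesterone receptor, stood at 7.74 ± 2.07 against 3.99 and 4.08. TFF1, a secreted trefoil peptide, was at 9.40 ± 2.79 against 4.93 in BT-20 but 11.32 in MDA-MB-157. No gene passed limma's test over the 12 lines (0 of 11865 at adjusted p under 0.05, 336 at unadjusted p under 0.05, lowest adjusted p = 0.222). Without MCF-7 and MDA-MB-175-VII, 1 gene passed and 769 had an unadjusted p under 0.05. It was BTNL9, a butyrophilin-like membrane protein, lower in the ER-positive lines by limma (4.91 ± 0.43 in 8 lines against 7.92 in BT-20 and 7.62 in MDA-MB-157, difference -2.87, adjusted p = 0.0432). Of the 23 lists, 0 differed between the labels, with every adjusted p at 1 in the exact permutation test, in which at least 7 lists would have had to reach the smallest possible p of 0.0152 for any to pass. The lowest unadjusted p, 0.0455, was that of the endothelial list, which was higher in both ER-negative lines. The comparison had 2 ER-negative lines, 1 of them with luminal markers.

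At 10 nM E2, ER target genes rose over the 8 ER-positive lines left after MCF-7 and MDA-MB-175-VII were set aside, a selection made after the data were seen. EGR3, an early growth response transcription factor, rose by 1.48 ± 0.80 log2 units (SD, n = 8 lines, limma adjusted p = 0.0298) and was higher in 8 of 8 lines. GREB1 rose by 1.49 ± 1.14 (limma adjusted p = 0.0322) and PGR by 1.08 ± 0.87 (0.0346), both in 8 of 8 lines. PDZK1, a scaffold of membrane transporters, rose by 1.5 ± 1.06 (0.0306) in 8 of 8. TFF1 had the largest mean change, 1.59 ± 1.54 (0.0484), and was higher in 7 of 8, with -0.17 in MDA-MB-134-VI. The other 5 of the 10 largest rises, all of them higher in 8 of 8 lines, were MPPED2, a metallophosphoesterase, at 1.20 ± 1.03, PMAIP1, which encodes the BH3 protein NOXA, at 1.19 ± 0.97, MYBL1, a MYB family factor, at 1.17 ± 0.67, RBM24, an RNA-binding protein, at 1.12 ± 0.94, and HEY2, a Notch pathway repressor, at 1.02 ± 0.67. MYB, a proto-oncogene and ER target, rose by 0.44 ± 0.35 (limma adjusted p = 0.0373).

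Among the genes that fell, IL1R1, the interleukin receptor gene, had the largest change, -0.99 ± 0.54 (SD, n = 8 lines, limma adjusted p = 0.0298), and was lower in all 8 lines. TP53INP1, a stress-response gene, fell by 0.97 ± 0.84 (0.0411). CCNG2, a cyclin linked to arrest, changed by -0.73 ± 0.55 (0.0319), ERBB2 by -0.64 ± 0.36 (0.0298), and BIK, a pro-apoptotic gene, by -0.43 ± 0.29 (0.0306), each lower in 8 of 8. The remaining 7 of the 10 largest falls were PPP3R1, a calcineurin subunit, at -0.80, CTSZ, a lysosomal protease, at -0.79, BLNK, a signalling adaptor, at -0.77, ARL15, a small GTPase, at -0.76, ERGIC1, a secretory pathway protein, at -0.74, PBX2, a homeobox factor, at -0.74 and BCAS1, a gene amplified in breast cancer, at -0.74. CTSZ and PBX2 were lower in 7 of 8 lines and the others in 8 of 8, and another probe set of CTSZ moved the opposite way. ESR1 itself did not pass (-0.15 ± 0.19, limma adjusted p = 0.133), nor did the chemokine gene CXCL12 (1.05 ± 1.36, 0.0929), MYC (1.08 ± 1.29, 0.0762), the cyclin genes CCND1 (0.22 ± 0.38, 0.204) and CCNE2 (0.50 ± 0.68, 0.109) or the proliferation marker MKI67 (0.50 ± 0.52, 0.0573).

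Grouped by the fixed lists, 26 of 46 measured oestrogen-induced ER targets rose and 20 did not pass (35 rose and 1 fell, adjusted over the list alone). Of 27 oestrogen-repressed targets, 12 fell and 15 did not pass (17 fell, adjusted over the list alone). Of 49 DNA replication genes, 12 rose and 37 did not pass (47 rose and 1 fell, adjusted over the list alone), among them ORC1 of the origin complex at 0.79 ± 0.49, CDC6, which loads the replicative helicase, at 0.79 ± 0.61, and the phosphatase CDC25A at 0.71 ± 0.54. For G2/M and mitosis, 2 of 40 rose, CDC25C at 0.44 ± 0.33 and the spindle protein PRC1 at 0.62 ± 0.52, and 38 did not pass (22 rose, adjusted over the list alone), MELK, a mitotic kinase, being just short (0.60 ± 0.57, limma adjusted p = 0.0505). Of 19 cell cycle inhibitors, 4 fell, such as KLF9, a growth-restraining factor, at -0.50 ± 0.34, and 15 did not pass (10 fell, adjusted over the list alone). Of 29 ribosome biogenesis genes, 7 rose, such as the nucleolar protein FBL at 0.36 ± 0.21 and the RNA-modifying enzyme PUS7 at 0.50 ± 0.35, and 22 did not pass (17 rose, adjusted over the list alone). LYAR, a nucleolar regulator, did not pass at 0.50 ± 0.49 (limma adjusted p = 0.0513). In the same limma fit 1039 of all 11865 genes passed and 3855 had an unadjusted p under 0.05. With so many, a count adjusted over a list alone is not by itself particular to that list.

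Over all 10 ER-positive lines, as designed, limma called 0 of 11865 genes at 10 nM (1318 at unadjusted p under 0.05, lowest adjusted p = 0.367). GREB1 changed there by 1.45 ± 1.28 (higher in 9 of 10 lines), EGR3 by 1.40 ± 1.00 (9 of 10), PDZK1 by 1.37 ± 0.99 (10 of 10) and IL1R1 by -0.997 ± 0.61 (lower in 10 of 10), none past the threshold (each at limma adjusted p = 0.367). With those 10 lines and adjusted over the list alone, 30 of the 46 oestrogen-induced targets, 38 of the 49 replication genes and 7 of the 27 repressed targets passed. In the same way, 0 of the 40 G2/M genes, 0 of the 19 cell cycle inhibitors and 0 of the 29 ribosome biogenesis genes passed. Over the 8 lines limma called 1039 genes, 463 higher and 576 lower, of which 10 rose by at least 2-fold and 0 fell by as much (3855 at unadjusted p under 0.05, lowest adjusted p = 0.0298). That count fell to 0 with trend and robust settings in limma and to 3 with the change of the spike level as a covariate, so nearly all single-gene calls at 10 nM depend on the fit. Without MCF-7 alone the count was 0, with a lowest adjusted p of 0.05001 and 3135 genes at unadjusted p under 0.05. The 8-line count was 0 when MDA-MB-361, BT-474, HCC1428 or T47D was left out as well. Over the 10 lines 948 of the 1039 genes had the same direction, and in each of the other fits all 1039 had. With trend and robust settings the mean change is the same by construction, so direction could not turn there. The others reuse all the remaining lines and so are a weak check of direction.

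**Figure D3:**
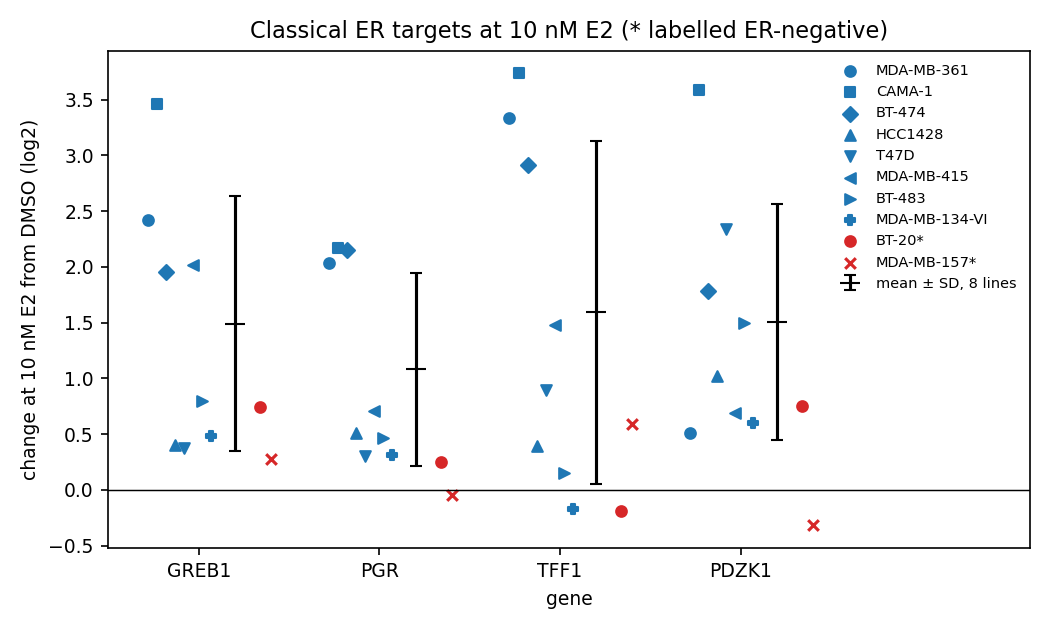
Change of 4 ER target genes at 10 nM E2 from DMSO in log2 units (y axis) by gene (x axis), 1 point per line. The black bars give the mean ± SD over 8 ER-positive lines, 1.49 ± 1.14 for GREB1, 1.08 ± 0.87 for PGR, 1.59 ± 1.54 for TFF1 and 1.5 ± 1.06 for PDZK1, and the lines labelled ER-negative are in red.

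At 1 nM E2 the rises past the threshold over the same 8 lines were led by MYBL1 at 0.97 ± 0.53 (SD, n = 8 lines) and HEY2 at 0.87 ± 0.49. They were followed by PGLYRP2, a peptidoglycan-binding enzyme, at 0.80, SLC7A5, an amino acid transporter, at 0.76, IGFBP4, which binds insulin-like growth factors, at 0.74, MICB, a ligand of natural killer cells, at 0.65, SIAH2, a ubiquitin ligase, at 0.58, SNX24, a sorting nexin, at 0.56, HAUS1, a spindle protein, at 0.51 and CHEK1, a checkpoint kinase, at 0.38. All had a limma adjusted p of 0.0489 and were higher in 8 of 8 lines except MICB, in 7, and another probe set of CHEK1 moved the opposite way. The largest falls past the threshold were those of BCAS1 at -0.72 ± 0.40 and BLNK at -0.70 ± 0.43. Next were SHISA2, a Wnt and FGF pathway modulator, at -0.53, TMCC3, a membrane protein, at -0.51, PRR15, a proline-rich protein, at -0.49, SLC12A2, an ion cotransporter, at -0.47, RAB27B, a secretory GTPase, at -0.44, CITED2, a transcriptional coregulator, at -0.43, RNF144B, a ubiquitin ligase, at -0.43 and SYT17, a synaptotagmin, at -0.42. Each was lower in 8 of 8 lines, and another probe set of CITED2 moved the opposite way.

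The classical targets were of similar size at 1 nM but missed the threshold in limma, with GREB1 at 1.19 ± 1.16 (adjusted p = 0.0671), PGR at 0.94 ± 0.75 (0.0538), TFF1 at 1.42 ± 1.37 (0.0659), PDZK1 at 1.42 ± 1.12 (0.0530) and EGR3 at 1.26 ± 0.93 (0.0517). The same held for MYC at 0.97 (limma adjusted p = 0.0938), CXCL12 at 0.95 (0.100), MYB at 0.35 (0.0517), CCNG2 at -0.63 (0.0575), ERBB2 at -0.53 (0.0587), BIK at -0.34 (0.0730), TP53INP1 at -0.85 (0.0688) and IL1R1 at -0.84 (0.0517). Of the oestrogen-induced targets 5 rose (35 rose and 1 fell, adjusted over the list alone), of the repressed targets 2 fell (18 fell and 1 rose, adjusted over the list alone), and of the replication genes 1 rose (47 rose and 1 fell, adjusted over the list alone). In all, limma called 62 genes over the 8 lines, 27 higher and 35 lower (3401 at unadjusted p under 0.05), against 0 with trend and robust settings and 1393 with the spike covariate. Over the 10 lines, as designed, it called 0 (1085 at unadjusted p under 0.05, lowest adjusted p = 0.473). The 8-line count ranged from 0 to 297 when 1 line was left out, the latter without CAMA-1 and 0 without any of the others.

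Both doses were compared with the same DMSO arrays, which makes their changes agree in part with no effect. All 62 genes called at 1 nM had the same sign at 10 nM, as had 1033 of the 1039 genes called at 10 nM at 1 nM. Over the latter the median ratio of the 1 nM to the 10 nM change was 0.773. Those genes were selected on their 10 nM change, which can lower this ratio by itself. The ratio also takes in MDA-MB-361 and was not simulated, so it does not measure the relative strength of the doses. In simulated arrays with no effect and the same shared DMSO, 56.6 of the 62 and 896 of the 1039 genes with the lowest p agreed in sign on average. Called at both doses were 23 rising genes, against 1.05 for independent lists and 10.1 in that simulation, and 32 falling genes, against 1.70 and 13.7, so part of the overlap may come from the shared arrays. Across genes a correlation of 0.5004 arises with no effect, and the one observed was 0.927, with a covariance of 0.0262 against a simulated 0.00184. With 1 nM taken from 4 of the lines and 10 nM from the other 4, the correlation across genes was 0.7101, and 0.699 the other way round. Of the 1039 genes with the lowest p at 10 nM in 4 lines, 955 had the same sign at 1 nM in the other 4, and 958 the other way round.

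Between 10 and 1 nM, EPOR, the erythropoietin receptor gene, was lower at 10 nM by limma over the 10 ER-positive lines (-0.30 ± 0.10 SD, adjusted p = 0.00944, lower in 10 of 10). Both other probe sets of EPOR moved the opposite way, so the call rests on 1 probe set. Over the 8 lines its change was -0.29 (limma adjusted p = 0.123) and 0 genes passed (1111 at unadjusted p under 0.05, against 1435 with 10 lines). GREB1 differed by 0.30 ± 0.85, PGR by 0.14 ± 0.62 and TFF1 by 0.17 ± 0.54 over the 8 lines, none past the threshold (limma adjusted p = 0.716, 0.825 and 0.743). No list shifted between the doses, the oestrogen-induced list by 0.095 (exact sign-flip adjusted p = 0.834). MDA-MB-361, a line with high ERBB2, lay apart from the others in this comparison. In it GREB1 changed by 0.20 at 1 nM and 2.42 at 10 nM, PGR by 0.40 and 2.03, TFF1 by 1.85 and 3.34, CXCL12 by 0.67 and 2.42, and MYC by 1.39 and 2.64. Over the 915 genes called in that line, the slope of the 1 nM on the 10 nM change was 0.513, against 0.886 to 0.957 in the 5 other such lines with over 100 called genes.

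In the lines labelled ER-negative, GREB1 changed at 10 nM by 0.75 in BT-20 and 0.28 in MDA-MB-157, TFF1 by -0.19 and 0.59, PGR by 0.25 and -0.04, PDZK1 by 0.76 and -0.32, and CXCL12 by -0.04 and 0.62. Under the filter level of 5.47, in DMSO and at 10 nM, were GREB1, PGR and PDZK1 in both lines, and TFF1 and CXCL12 in BT-20. GREB1 in BT-20, for example, stood at 3.84 at 10 nM. The changes of these genes there are limited by an unknown floor and show neither a response nor its absence. In MDA-MB-157 the proto-oncogene MYC changed by 0.26 at 1 nM and 1.10 at 10 nM, and EGR3 by 0.53 and 1.95. Limma called 0 genes at 10 nM (17 at unadjusted p under 0.05) and 0 at 1 nM (41), and without MCF-7 and MDA-MB-175-VII in the shared spread 0 and 0 (187 and 356). The difference in response between ER-positive and ER-negative lines also gave 0 genes (41 at unadjusted p under 0.05, and 497 without those 2 lines). PGR had a difference of 0.98 over the 8 and 2 lines and did not pass (limma unadjusted p = 0.0526, adjusted p = 0.884). The counts at unadjusted p under 0.05 given here all lie below 0.05 of the 11865 genes, the share that tests with no effect would give. The shared spread takes in the differing responses of the ER-positive lines, so 0 calls say little about the ER-negative lines. A response in the receptor-positive lines only was thus not shown by this test, which had 2 lines on one side.

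Line by line, the E2 arrays were set against DMSO with both doses averaged. In CAMA-1 limma called 4573 genes, with TFF1 at 3.70, PDZK1 at 3.61, the phosphatase gene PPM1E at 3.61, the GTPase gene GEM at 3.60 and CXCL12 at 3.42 in the lead, and with TP53INP1 at -2.78 and the stress gene DDIT4 at -2.54 as the largest falls. Among the 8 lines other than MCF-7 and MDA-MB-175-VII, T47D followed with 1807 calls, led by MPPED2 at 2.34, EGR3 at 2.31 and PDZK1 at 2.26. MDA-MB-361 had 915, led by the vitamin B12 binder TCN1 at 2.62 and TFF1 at 2.59, and BT-474 had 812, led by MYC at 3.05, TFF1 at 2.98 and the steroid-responsive gene SUSD3 at 2.51. MDA-MB-134-VI had 187, with PGLYRP2 at 1.46 and IL1R1 at -1.37 as the extremes. HCC1428 had 169, with the coregulator CITED1 at 1.51 and the membrane protein TMEM150C at -1.32. MDA-MB-415 had 9, led by the reductase DHRS2 at 1.54, and BT-483 had 5, led by PDZK1 at 1.37 and the prostaglandin synthase PTGES at 1.00.

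Of the lines labelled ER-negative, MDA-MB-157 had 4 calls in limma, the junction protein CGN at 1.05, IGFBP5, which binds insulin-like growth factors, at 1.02, the ligand WNT9A at -1.22 and the transcript ANXA2R-OT1 at -0.68. BT-20 had 1, the phosphatase PTPRS at 0.51. MCF-7 had 9670 calls, 8509 of them higher, which rest on its DMSO array: the median gene moved by 0.81 there, and with quantile normalization by 0.03, with 5221 higher and 5011 lower calls. MDA-MB-175-VII had 2688 calls, 811 higher and 1877 lower, with the median gene at -0.08, and with quantile normalization 1586 higher and 697 lower, with the median gene at 0.04, so its direction depends on the scaling. In T47D 1346 calls were higher and 461 lower, and with quantile normalization 1081 and 596. The E2 arrays of MDA-MB-175-VII carry another service code than its DMSO array, so in this line E2 and service order cannot be told apart. In the per-line fit the 1 DMSO array is assumed to vary like the E2 arrays. The numbers describe these arrays and not repeated cultures.

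**Figure D4:**
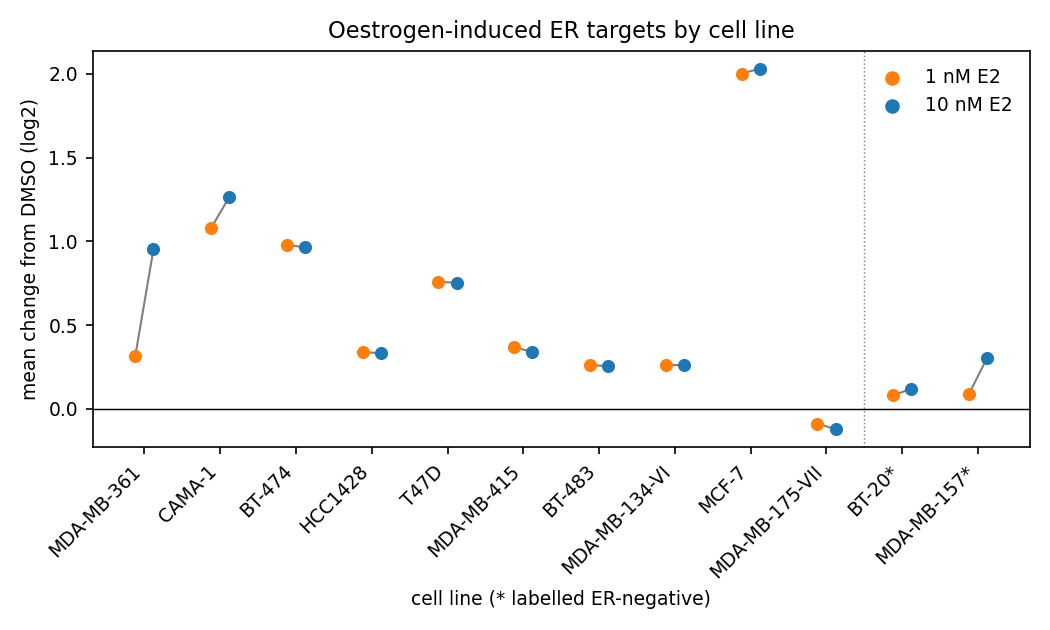
Mean change of 46 oestrogen-induced ER targets from DMSO in log2 units (y axis) at 1 and 10 nM E2 for each of 12 cell lines (x axis), 1 point per line and dose. The 8 ER-positive lines other than MCF-7 and MDA-MB-175-VII lie between 0.25 and 1.26, MCF-7 at 2.0 and 2.03 on its deviating DMSO array, and MDA-MB-175-VII at -0.09 and -0.12.

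Taken per list and averaged over both doses, the oestrogen-induced targets shifted by 0.59 ± 0.35 (SD) over the 8 lines, up in 8 of 8, and the oestrogen-repressed targets by -0.35 ± 0.26, down in 8 of 8. DNA replication shifted by 0.50 ± 0.48, G2/M and mitosis by 0.31 ± 0.34, ribosome biogenesis and MYC targets by 0.26 ± 0.25, each up in 8 of 8, and the cell cycle inhibitors by -0.20 ± 0.14, down in 8 of 8. These 6 of 23 lists passed (exact sign-flip p = 0.00781, the smallest possible, adjusted p = 0.0299). Camera with a preset correlation called them too, but each had an adjusted p = 0.535 with an estimated correlation. Over the 10 lines, as designed, 0 lists passed, and 6 had an unadjusted p under 0.05. There the oestrogen-induced list shifted by 0.66 ± 0.61 (up in 9 of 10, exact sign-flip p = 0.00391, adjusted p = 0.0898), replication by 0.62 ± 0.80 (0.0117, adjusted 0.135), G2/M by 0.43 ± 0.68 (0.0352, adjusted 0.135), ribosome biogenesis by 0.38 ± 0.60 (0.0215, adjusted 0.135), the repressed targets by -0.19 ± 0.44 (0.211, adjusted 0.485) and the inhibitors by -0.02 ± 0.59 (0.986, adjusted 0.990).

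The heat shock and chaperone list shifted by 0.20 ± 0.17 over the 8 lines, up in 7 of 8, and did not pass with both doses (exact sign-flip adjusted p = 0.0513), while at 10 nM alone it did (0.21, up in 8 of 8, adjusted p = 0.0359). With both doses, camera called it with a preset correlation (adjusted p = 0.000729) but not with an estimated one (0.535). Cholesterol biosynthesis moved by 0.083 (exact sign-flip adjusted p = 0.135) and the nuclear receptors by -0.032 (0.220). The unfolded protein response moved by 0.040, the androgen and glucocorticoid targets by -0.055, the aryl hydrocarbon receptor targets by -0.020, the pro-apoptotic list by -0.035, the anti-apoptotic list by -0.063, insulin signalling by 0.051 and the immediate early genes by 0.0062. Hypoxia moved by -0.014, the interferon-stimulated genes by -0.0029, the luminal markers by 0.00092, the basal markers by -0.045, and the immune, fibroblast and endothelial lists by 0.043, -0.0078 and -0.025. None of the latter 14 lists passed in the exact sign-flip test over the 8 lines. At 10 nM the median member went against the mean in the insulin list (-0.10 against 0.068) and the interferon list (-0.039 against 0.011).

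Among the 8 lines the oestrogen-induced shift was largest in CAMA-1 at 1.17, followed by BT-474 at 0.97, T47D at 0.76 and MDA-MB-361 at 0.63. It was 0.35 in MDA-MB-415, 0.34 in HCC1428 and 0.26 in both BT-483 and MDA-MB-134-VI. No relation of this shift with the DMSO level of ESR1 was shown over the 10 lines (r = 0.13, permutation p = 0.693, rho = -0.16, p = 0.658). Both measures of MCF-7 rest on its deviating DMSO array, where ESR1 stood at 8.39 against 10.85 and 10.96 on its E2 arrays. Without MDA-MB-134-VI and MDA-MB-175-VII, farthest from the median, r was -0.61, so the value over 10 lines depends on single lines. Over the 8 lines r was -0.45 (exact permutation p = 0.258, rho = -0.43, p = 0.299). Over the 10 lines, MCF-7 with its deviating DMSO array among them, the shift of the proliferation lists rose with that of the ER targets (r = 0.92, permutation p = 0.00109, adjusted p = 0.00218, rho = 0.78, p = 0.0108, adjusted p = 0.0216). Without CAMA-1 and MCF-7, farthest from the median, r was 0.61 (permutation p = 0.111). Over the 8 lines the relation did not pass after adjustment, with r = 0.70 (exact permutation p = 0.0488, adjusted p = 0.0976, rho = 0.57, p = 0.151, adjusted p = 0.299), and r was 0.85 without CAMA-1 and BT-474. In BT-474 the replication list shifted by 0.23 beside an ER shift of 0.97, and in MDA-MB-361 by 0.99 beside 0.63. These were the 2 relations of the family, and in both of them the 2 measures share the DMSO arrays.

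The change of the poly-A spike level from DMSO, a measure of quality set against the ER response after the data were seen, moved with the oestrogen-induced shift. Their r over the 8 lines was 0.85 (exact permutation p = 0.00880, adjusted p = 0.0176, rho = 0.81, p = 0.0218, adjusted p = 0.0436), and 0.78 without CAMA-1 and MDA-MB-134-VI, farthest from the median. With 10 lines r was 0.77 (permutation p = 0.00833, adjusted p = 0.0167, rho = 0.72, p = 0.0233, adjusted p = 0.0466), and 0.61 without MDA-MB-134-VI and MCF-7. The spike changed by 1.27 in CAMA-1, 1.12 in T47D, 0.68 in BT-474, 0.30 in HCC1428 and 0.16 in MDA-MB-361, and by -0.37 in BT-483, -0.38 in MDA-MB-415 and -1.11 in MDA-MB-134-VI. The order of the 8 lines in the oestrogen-induced shift is thus not separate from this measure, which shares the DMSO arrays with it. Of the other lines, the spike changed by 1.96 in MCF-7, beside a shift of 2.02. In MDA-MB-157 it had the largest change of all lines, 2.20, beside a shift of 0.20. It changed by 0.53 in MDA-MB-175-VII beside -0.11 and by -0.34 in BT-20 beside 0.10. Between 10 and 1 nM, where no DMSO array enters, r was -0.25 over the 8 lines (exact permutation p = 0.379, adjusted p = 0.379, rho = -0.24, p = 0.582, adjusted p = 0.582), and -0.42 without CAMA-1 and BT-474. With 10 lines it was -0.25 (permutation p = 0.328, adjusted p = 0.328, rho = -0.09, p = 0.814, adjusted p = 0.814), and -0.21 without BT-474 and MCF-7. In BT-474 the spike changed by -0.52 at 1 nM and 1.87 at 10 nM, while the oestrogen-induced list moved by 0.98 and 0.96. These 2 relations formed a family of their own.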

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

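A sample was picked out for this part when its gap to the nearest of the other lines was large against the whole range of the group (Dixon's test). Of 57 groups of 8 or 10 ER-positive lines, 18 held such a sample, while chance gives about 1 in 20 for a single group. The groups are not independent: the same arrays return in several of them, and some genes count both singly and within a list. The 18 therefore cannot be measured against that rate. The tests of explanations below were chosen after the results were seen. No list or gene of the 37 compared moved one way in all 8 lines and the other way in both lines labelled ER-negative.

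The DMSO array of MCF-7 lay far from the DMSO arrays of the 9 other ER-positive lines in its standard deviation, 1.46 against 2.09 for the nearest, in the GAPDH 3′ minus 5′ difference, 3.69 against 0.05, and in that of actin, 5.82 against 2.66. A mislabelled array of another line of the panel is argued against, since its highest correlation with any such array was 0.548 and both E2 arrays of MCF-7 lay above that, at 0.607 and 0.610. A response of MCF-7 to E2 is argued against as well, because both ends of the GAPDH transcript would move together, whereas the 5′ end moved 3.75 more than the 3′ end between DMSO and E2, against -0.37 to 0.25 in the 11 other lines. Degraded RNA, or copying from the 3′ end that stopped early, may explain the array, since the actin difference of 5.82 lay above the 1.30 to 2.66 of the other 35 arrays. A fault of labelling or scanning was not tested and stays open.

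In the line labelled MDA-MB-175-VII the DMSO level of ESR1 was 3.61, where the next of the 10 ER-positive lines had 8.39, and the luminal minus basal score in DMSO was -4.53, where the next had 0.82. Both next values come from the deviating DMSO array of MCF-7. In the 8 other lines the lowest were 8.80 and 1.43. Its second service code is argued against as the source, since the DMSO array, with the code of the other lines, had that score of -4.53, and so is degraded RNA, since the highest actin difference on the 6 arrays labelled MDA-MB-175-VII and MDA-MB-157 was 2.12, within the range of the other lines up to 2.66. A candidate explanation is that the names of these lines were exchanged: the score of MDA-MB-157 lay 8.58 above that of MDA-MB-175-VII, within the range of the 8 other ER-positive lines, and the score of MDA-MB-175-VII lay below BT-20. Other values go with the label of MDA-MB-157 in part. GREB1 and PGR stood at 3.49 and 4.08 in its DMSO array, near the 3.09 and 3.99 of BT-20 and below the mean of 8.35 and 8.09 in the 8 lines, whereas TFF1 stood at 11.32. PGR was also low, at 4.43, in MDA-MB-134-VI, the line of the 8 with the highest ESR1. At 10 nM PGR changed in MDA-MB-157 by -0.04 and PDZK1 by -0.32, but GREB1 by 0.28, TFF1 by 0.59, CXCL12 by 0.62 and MYC by 1.10. Of these, PGR, PDZK1 and GREB1 stayed under the filter level of 5.47 in that line, where an unknown floor limits a change. In MDA-MB-175-VII, labelled ER-positive, GREB1 and PGR stood at 3.97 and 5.42 in DMSO. The oestrogen-induced list moved by 0.20 in MDA-MB-157 and 0.10 in BT-20, both at percentile 100 of 10000 random lists, and by -0.11 in MDA-MB-175-VII (39.2), against 0.26 to 1.17 in the 8 lines. The repressed list lay at percentile 6.31, 50.3 and 98.7 in these 3 lines, against 0 in each of the 8. Stocks of these lines that differ from the usual ones stay open and untested, and every result by ER label depends on this.

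In MDA-MB-361 the 10 nM minus 1 nM differences lay far above those of the 7 other lines for the oestrogen-induced list at 0.64 (next 0.18), replication at 0.63 (0.09), G2/M at 0.43 (0.06), GREB1 at 2.22 (0.69), PGR at 1.63 (0.07), TFF1 at 1.49 (0.11) and CXCL12 at 1.76 (0.14), and far below for the oestrogen-repressed list at -0.34 (next -0.0063). Degraded RNA on its 1 nM array is argued against by an actin difference of 1.96, within the range of the other arrays. The 1 nM changes followed the 10 nM changes with a slope of 0.513 and r = 0.952 over 915 genes. Both changes share 1 DMSO array and the genes were called on their mean, so part of this r arises by construction. The share varied by gene (0.20 of 2.42 for GREB1, 1.85 of 3.34 for TFF1) and by list (0.31 of 0.95 for the oestrogen-induced targets, 0.68 of 1.31 for replication). A sample that received part of the dose and a line that needs more E2 would both give smaller changes. With 1 array per dose these cannot be told apart. The 20% serum in which the line was maintained is argued against as the only source, since BT-483 and MDA-MB-134-VI had it too and their 10 nM minus 1 nM differences of the oestrogen-induced list were -0.0086 and 0.0031, against up to 0.18 in the 5 lines kept in 10%. The added insulin was shared with BT-483 alone, whose difference of -0.0086 goes against it, but 1 line does not exclude it.

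Also far from the other 7 lines were CAMA-1 in the shift of the oestrogen-repressed list (-0.96, next -0.41), CCNG2 (-1.84, next -0.82) and BIK (-1.04, next -0.51), and BT-483 in the immune list of 4 measured genes (-0.11, next 0.02). The 1 nM array of MDA-MB-175-VII had a standard deviation of 2.03, where the next of the 10 lines had 2.08. Its 10 nM array had 2.04 and its DMSO array 2.10. Only the 1 and 10 nM arrays of this line carry the second service code. No explanation of these was tested.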

How the results depend on the processing

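The comparison over 8 lines and its alternatives, the weighting of lines by arrayWeights and the spike level as a covariate were chosen after the results were seen, and the other alternatives before. Of the gene counts over several lines that of 10 nM over 8 lines was the largest, and its adjusted p-values lie between 0.0298 and the threshold, so small changes of the fit move it across. The cause was not tested for any change below, except where the construction shows it: fewer lines, fewer genes tested or a spread that counts the differences between lines. In the 8 lines the median gene moved by -0.0076 as deposited and -0.0075 with quantile normalization. The medians of these arrays were alike as deposited, and quantile normalization makes them so. These values therefore cannot show whether all genes shifted together. The values give no signal over background, so genes near the filter level are limited by an unknown floor.

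At 10 nM, the 8-line count of 1039 was 466 with no filter (more genes tested), 0 with trend and robust settings, 580 with weighted lines, 3 with the spike covariate, 3180 with all 3 exposures in 1 fit, 0 with MDA-MB-175-VII added and 0 with all 10 lines. With no replicate block it was 0, since the pairing removes the differences between lines. All 1039 genes kept their direction in each of these but that over 10 lines, where 948 did. With no filter, trend and robust settings, no block or all 3 exposures the mean change is the same by construction. Direction could not turn in those fits. The mean of all probe sets called 766 genes, 579 of them shared, and 998 of the 1002 genes with a value there kept their direction. Quantile normalization called 1227 genes, 1023 of them shared, and median centring 992, 990 of them shared. Leaving out 1 line gave 0 to 1034: 0 without MDA-MB-361, BT-474, HCC1428 or T47D, 249 without CAMA-1, 295 without MDA-MB-415, 865 without MDA-MB-134-VI and 1034 without BT-483. Over the 10 lines the count of 0 became 193 (115 up, 78 down) with all 3 exposures in 1 fit, 871 (310 up, 561 down) with weighted lines and 1039 without both lines, and stayed at 0 to 0 on leaving out 1 line.

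At 1 nM, the 8-line count of 62 was 99 with quantile normalization, 0 with median centring, 0 with no filter, 690 with the 60% filter, 114 with the mean of probe sets, 0 with every probe set by itself, 0 with trend and robust settings, 1138 with all 3 exposures, 437 with weighted lines, 1393 with the spike covariate, 13 with MDA-MB-175-VII and 0 with all 10 lines, and 0 with no replicate block, which ignores the pairing. Leaving out 1 line gave 0 to 297, the latter without CAMA-1. Over the 10 lines the count of 0 became 2 with all 3 exposures, 858 with weighted lines and 62 without both lines, with 0 to 13 on leaving out 1 line (13 without MCF-7). The EPOR call between the doses was lost, to 0 genes, with the mean of probe sets, trend and robust settings, no replicate block (no pairing), all 3 exposures and without both lines, and leaving out 1 line gave 0 to 1.

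For ER-negative lines the count at 10 nM was 2 when fitted alone (1 up, 1 down), and leaving out 1 line gave 0 to 0 at 10 nM and 0 to 1 at 1 nM, 1 without BT-20. In DMSO the count was 2 with no filter, 1 without MDA-MB-175-VII, 1 without both lines and 0 to 3 on leaving out 1 line, 3 without MDA-MB-157. For the difference in response it was 0 to 0. Per line, each dose alone called 50 genes at 1 nM and 2152 at 10 nM in MDA-MB-361, 263 at 1 nM in BT-474, 752 at 1 nM in T47D, 61 and 87 in HCC1428, 76 and 87 in MDA-MB-134-VI, 2 and 3 in MDA-MB-415, 1 and 1 in BT-483, 1 at 10 nM in MDA-MB-157, 0 at 10 nM in BT-20 and 1135 at 10 nM in MDA-MB-175-VII. With no filter the calls were 2 in BT-20, 3 in MDA-MB-415, 3 in BT-483 and 121 in MDA-MB-134-VI, and quantile normalization gave 4 in BT-20.

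Over the 10 lines 0 lists passed, against 5 with quantile normalization, 7 by camera with a preset correlation, 5 without MDA-MB-175-VII and 6 without both lines, with 0 to 5 on leaving out 1 line. Over the 8 lines 6 passed, against 0 by camera with an estimated correlation, and 0 to 0 on leaving out 1 line, where 6 or 7 lists reached the smallest p possible with 7 lines (0.0156) and at least 8 of 23 would have to reach it to pass. The correlation of ESR1 with the ER response turned from 0.13 to -0.61 without the 2 farthest lines, to -0.65 without MDA-MB-175-VII and to -0.45 without both lines. That with the proliferation response fell to 0.61 without the 2 farthest lines. The other counts stayed within 1.5 times in the alternatives run. Of single named genes over the 8 lines, 171 tests at 10 nM lost the threshold, 11 gained it and 280 kept their side in these alternatives, and 120, 71 and 366 at 1 nM. On leaving out 1 line these numbers were 150, 4 and 158 at 10 nM and 140, 11 and 225 at 1 nM. For single lists over the 8 lines these numbers were 8, 6 and 170, G2/M and the cell cycle inhibitors being lost at 10 nM alone, and on leaving out 1 line 48, 0 and 136. With 10 lines they were 0, 23 and 207, and on leaving out 1 line 0, 5 and 225. None that had passed turned in direction. Leaving out the pairing changed no other count of genes.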

Other observations

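Over the 8 lines at 10 nM, 6 of 24 measured luminal markers fell and 1, TFF1, rose, while 17 did not pass in limma (2 rose and 7 fell, adjusted over the list alone). The genes of this part were chosen after their values were seen. The luminal list as a whole moved by 0.0024 and did not pass. Over all 11865 genes 1039 passed in limma and 3855 had an unadjusted p under 0.05. The counts over a list alone in this part are therefore not by themselves particular to a list. Lower among the luminal transcription factors were FOXA1, which opens chromatin for ER, by -0.48 ± 0.26 (SD, n = 8 lines, limma adjusted p = 0.0298, lower in 7 of 8), GATA3 by -0.49 ± 0.32 (0.0306, 8 of 8), SPDEF by -0.36 ± 0.24 (0.0307, 8 of 8) and ELF3 by -0.50 ± 0.30 (0.0298, 7 of 8). The tight junction gene CLDN4 fell by 0.46 ± 0.24 and the keratin gene KRT7 by 0.38 ± 0.21 (both 0.0298). Among the nuclear receptors and ER cofactors 4 of 21 rose, 6 fell and 11 did not pass (5 rose and 8 fell, adjusted over the list alone). RARA, a retinoic acid receptor, rose by 0.40 ± 0.26, NRIP1, an ER corepressor, by 0.38 ± 0.26 and TFAP2C by 0.43 ± 0.33, whereas its relative TFAP2A changed by -0.33 ± 0.29, the retinoid partner RXRA by -0.34 ± 0.29 and the thyroid hormone receptor THRA by -0.20 ± 0.08 (limma adjusted p = 0.0306 to 0.0495).

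Of the apoptosis genes, the death receptor FAS rose by 0.32 ± 0.18 (limma adjusted p = 0.0306) beside PMAIP1, while BIK and TP53INP1 fell, and 10 of 14 pro-apoptotic genes did not pass (3 rose and 4 fell, adjusted over the list alone). CYP1A1, the main target of the aryl hydrocarbon receptor, changed by -0.33 ± 0.25 (limma adjusted p = 0.0395, lower in 7 of 8 lines) and TIPARP, another of its targets, by 0.42 ± 0.32 (0.0346, higher in 8 of 8), and 6 of 8 genes of that list did not pass (1 rose and 3 fell, adjusted over the list alone). In cholesterol synthesis FDPS rose by 0.35 ± 0.30, EBP by 0.34 ± 0.31 and HSD17B7, which also makes oestradiol, by 0.25 ± 0.12 (limma adjusted p = 0.0306 to 0.0481), and 15 of 18 did not pass (6 rose and 1 fell, adjusted over the list alone). Of 14 heat shock genes 3 rose, the steroid receptor cochaperone FKBP4 at 0.67 ± 0.42, the mitochondrial chaperone HSPD1 at 0.31 ± 0.23 and HSPA4 at 0.20 ± 0.14 (limma adjusted p = 0.0298 to 0.0461), and 11 did not pass (7 rose and 1 fell, adjusted over the list alone).

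Whether a weak ER response exists in the lines labelled ER-negative stays open, and the comparison with random lists was chosen after the values were seen. In the arrays labelled MDA-MB-157 the oestrogen-induced targets moved by 0.20 over both doses, at percentile 100 of 10000 random lists of like level, and by 0.09 at 1 nM and 0.30 at 10 nM. In BT-20 they moved by 0.10, also at percentile 100, with 0.08 and 0.12 at the doses. These percentiles restate the rise and do not give its origin. In BT-20 they are not particular to ER targets, since the replication list lay at percentile 100 too (0.07), while in MDA-MB-157 it lay at 94.9 (0.05). The repressed targets moved by -0.05 in MDA-MB-157 (percentile 6.31) and 0.01 in BT-20 (percentile 50.3), against percentile 0 in each of the 8 lines. Each percentile describes 3 arrays, and a deviation of the 1 DMSO array of a line could give the same. In MDA-MB-157 that array had a spike level of 5.91 against 8.51 and 7.71 on the E2 arrays, and an actin 3′ minus 5′ difference of 1.30, the lowest of the 36, against 2.05 and 2.12.

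Other assignments of the exposures within lines, 100 with the real one for each count, were set against the real counts. For 10 nM over the 8 lines 1 of 100 gave as many genes, the real one with 1039, against 0 for the highest other. For 1 nM it was 1 of 100 too, the real one with 62 against 0. Within these 8 lines the other assignments thus did not reach the real counts. The lines were chosen after the data were seen and the draws do not cover that choice, so they do not exclude chance for it. The real counts over the 10 lines were 0 at 10 nM and at 1 nM, which any assignment matches (100 of 100 each), so these say nothing about chance. For 10 against 1 nM, 2 of 100 gave as many, the real one with 1 gene and another with 1. In the latter HCC1428, BT-483, MDA-MB-134-VI, MCF-7 and MDA-MB-175-VII changed places. Another assignment thus matched the real count, and a count of 1 gene that rests on 1 of 3 probe sets does not exclude chance.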
